A study of Mus musculus with 26 samples.

How the data were processed

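The series holds 26 arrays of total RNA from mouse heart, taken after TAC or sham surgery at 48 h, 10 d and 3 wk. Groups, durations and replicate numbers are those of the labels, and every array has a group. The array type is MG_U74Av2 per the array description files, and the deposited values are intensity on a linear scale, 1 per probe set and array, from 0.4 to 335354.1. Each array seems to have been scaled to one level before deposit, which no source used here states: the mean left after trimming 2% at each end lies between 2501.81 and 2502.2 on all arrays. The method that summarised the probes is not given in the sources used here. Array medians were 741 to 1031. The number of arrays limits the precision.

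Values were used as deposited, without further scaling. Values below a floor, the 20th percentile of all values (167.9, or 7.39 on the log2 scale), were set to it, and log2 values were taken. Of 12488 probe sets, 66 controls were left out, and those above the pooled median of 880.1 in at least 4 arrays were kept, which left 7297. By the probe table given with the series, 10833 probe sets name 1 gene, 396 several and 1193 none; of those tested these numbers were 6584, 248 and 465, and 10817 of the symbols stand in the RefSeq gene table. Each gene was represented by the tested probe set with the highest mean (5564 genes), and where another probe set of a named gene moved the other way the text says so. No genome was used, so no positions are given.

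One limma model (lmFit, then eBayes with an intensity trend) had a mean for each of the 6 groups, so that all arrays share 1 estimate of the spread. It tested TAC against sham at each duration, the 3 differences of that effect between durations, and by an F test the 3 sham groups, with 10 d and 3 wk sham also tested against 48 h sham. P-values were adjusted by Benjamini and Hochberg over the 7297 probe sets, and an adjusted p under 0.05 is a call. Log2 changes are TAC minus sham. Overlaps were tested by Fisher's exact test, and RNA quality ratios by two-sided exact permutation tests.

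The comparisons, the main settings, the alternatives, the gene lists and the rule for named genes were set before the data were examined. The rule names, for TAC against sham, (a) the 10 largest rises and the 10 largest falls among calls whose TAC arrays all lie on one side of all sham arrays, (b) of each list described, up to 4 passing members with the largest change or, if none passed, the 2 with the highest level, and (c) always Nppa, Nppb, Myh6, Myh7, Acta1, Atp2a2, Ankrd1, Col1a1, Col3a1, Fn1, Postn and Ccn2. For differences between durations it names the 5 largest each way, and for the sham groups the 6 smallest p-values. The members of lists that did not pass as a list are named where they passed themselves.

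The 22 gene lists covered hypertrophy markers, sarcomere, calcium handling, ion channels and connexins, collagens, matrix glycoproteins and assembly factors, matrix proteases and inhibitors, fatty acid oxidation, glycolysis and glucose uptake, the citric acid cycle and oxidative phosphorylation, immediate early genes, cell cycle, cytokines with chemokines and adhesion molecules, growth factor signalling, natriuretic with renin, adrenergic and endothelin genes, cytoskeleton, heat shock and endoplasmic reticulum stress, antioxidant and detoxification genes, protein degradation, translation, apoptosis and clock genes. The 14 marker lists covered macrophages and monocytes, lymphocytes, neutrophils and mast cells, fibroblasts, endothelium, smooth muscle and pericytes, erythroid cells, adipocytes, skeletal muscle, atrial muscle, mesothelium, lung epithelium, Schwann cells and neurons, and sex-linked transcripts. Mesothelial and sex-linked lists had fewer than 3 measured members and were not tested, which left 34 lists at 3 durations, or 102 tests. Some genes stand in more than 1 list (Nppa is a hypertrophy and an atrial marker; Lum and Mfap5 are matrix genes and fibroblast markers), so the lists are not independent. Lists were tested with camera at an inter-gene correlation of 0.01, again with an estimated correlation, and counted over all genes and over the list alone. Under the alternatives, lists were tested with cameraPR, which takes ranked statistics, so p-values differ slightly from those of camera.

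Scan day and chip lot came from the array description files, which give 5 scan days and none for 2 arrays. They were used to block by scan day and to take each duration's main scan day alone. Alternative settings chosen at the outset were quantile normalization, cyclic loess normalization, median centring, a floor at the 5th or 40th percentile, an offset in place of the floor, no filter, a filter at the 70th percentile, no intensity trend, robust eBayes, array weights, only the groups compared, replicate number or scan day as a block, each array left out in turn, a fold of at least 1.5, an unmoderated test per probe set with unequal variances, the probe set of largest interquartile range, and the estimated correlation. Replicate numbers were checked as a pairing. Added after the data were seen were each duration's main scan day alone, the 3 wk comparison without both TAC arrays of the second scan day, and the mean of Myl7 and Myl4 per array as a covariate.

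The calculation was tested on simulated data with 7297 genes of which 200 changed. At 48 h, 10 d and 3 wk it found 75.0%, 75.0% and 81.0% of genes changed by 1 on the log2 scale and 27.7%, 31.9% and 22.8% of those changed by 0.5. For differences between durations it found 55.9% (10 d against 48 h), 48.7% (3 wk against 10 d) and 52.4% (3 wk against 48 h) of those changed by 1. False calls numbered 4 to 12 per comparison. The share found depends on how many genes change, because the adjusted threshold is stricter when fewer pass. The simulated 48 h comparison gave 139 calls and the measured one 4. The shares above are therefore not the detection rate of the measured 48 h comparison, which can be lower. With simulated collagens shifted by 0.5, that list passed (adjusted p = 4.60e-12) and 0 of the 33 other lists did. Simulated genes varied independently of each other and held no scan-day differences. The simulation therefore does not test list calls where genes move together, as the measured collagens did (estimated correlation 0.417 in the 48 h test). Tools were R 4.3.3, limma 3.58.1, statmod 1.5.0, Python 3.11.15 and matplotlib 3.10.9.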

Results

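Gene expression was measured in mouse heart after transverse aortic constriction (TAC), surgery that narrows the aortic arch so that the left ventricle pumps against a raised pressure, and after sham surgery. The 26 arrays formed 6 groups: 4 sham and 5 TAC arrays at 48 h, 4 sham and 4 TAC arrays at 10 d, and 4 sham and 5 TAC arrays at 3 wk. Each array gave intensities for 12488 probe sets, with array medians from 741 to 1031, and 7297 probe sets were tested. The number of arrays limits the precision of every comparison, and p-values measure only the spread between these arrays, since nothing in the labels says that each array came from a separate animal.

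Arrays of one group correlated at r = 0.922 to 0.961 across probe sets (median 0.945), and arrays of different groups at 0.878 to 0.965 (median 0.920); probe sets are not independent replicates. Ratios of 3′ to 5′ signal of Gapdh and Actb, a sign of RNA integrity, did not pass a test between TAC and sham at any duration (two-sided exact permutation p from 0.143 to 0.886). The 48 h arrays shared 1 scan day. At 10 d, 7 arrays shared 1 scan day and TAC replicate 4 had another. At 3 wk, sham replicates 2 and 3 and TAC replicates 1, 2 and 3 shared 1 scan day, TAC replicates 4 and 5 had another, and sham replicates 1 and 4 have none in their array files. No known scan day held arrays of more than 1 duration, so among arrays with a known day duration and scan day cannot be told apart.

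**Figure D1:**
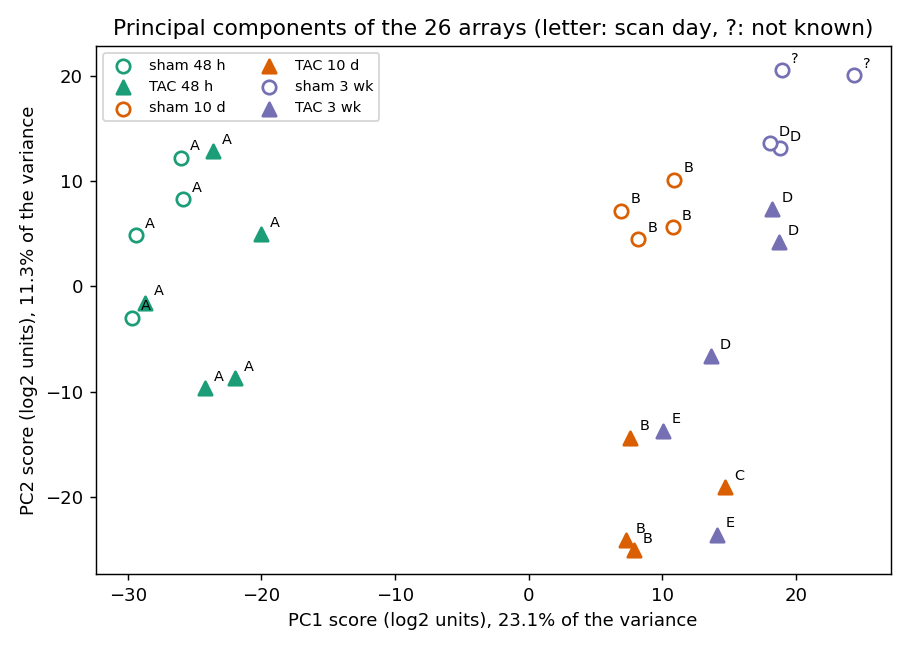
Each point is 1 of the 26 arrays on the first 2 principal components of the log2 values (PC1, 23.1% of the variance; PC2, 11.3%), coloured by group and lettered by scan day, with a question mark where none is known. The 48 h arrays lie at PC1 values from −29.7 to −20.0 and all other arrays from 6.95 to 24.4; at 10 d the TAC arrays lie from −25.0 to −14.4 on PC2 and the sham arrays from 4.48 to 10.1.

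The comparison at 48 h asked which transcripts differed between TAC and sham hearts early after constriction. Nppb, which encodes brain natriuretic peptide, a hormone that ventricular muscle releases when stretched, rose 3.40-fold (log2 1.77, SE 0.20, adjusted p = 1.28e-05). Its mean log2 intensity was 16.49 ± 0.46 (SD, n = 5) in TAC and 14.73 ± 0.34 (SD, n = 4) in sham arrays, and every TAC array lay above every sham array. Itgav, a matrix-binding integrin subunit, rose 1.54-fold (SE 0.11 on the log2 scale, adjusted p = 0.0283) and Perp, a membrane protein of cell junctions, rose 1.36-fold (SE 0.08, adjusted p = 0.0319), each with every TAC array above every sham array. A probe set of Cav3, the caveolin of muscle, rose as well (log2 0.58, adjusted p = 0.0283) and was chosen after its values were seen. It is not the probe set that represents Cav3 here, which was not called at 48 h.

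These 4 probe sets were the ones called by limma at 48 h, all higher in TAC, and 450 passed an unadjusted p of 0.05 where 364.85 would by chance. The call of Nppb held without each array in turn (log2 1.58 to 1.88) and under the 26 alternatives run gene by gene. These leave out the unmoderated test per probe set, which called no probe set at 48 h. Itgav was no longer called without sham replicate 1, 3 or 4 or TAC replicate 2 or 4 (adjusted p up to 0.139), and its other probe set read −0.03. Perp was no longer called without sham replicate 1, 3 or 4 or TAC replicate 1, 2, 3 or 4 (adjusted p up to 0.154). The count was 1 without TAC replicate 4, 2 without sham replicate 3, sham replicate 4, TAC replicate 1 or TAC replicate 2, and 8 without TAC replicate 5. It was 1 without an intensity trend or using only the groups compared, and 8 with replicate number as a block.

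Of the 14 measured hypertrophy marker genes, transcripts long used as signs of a loaded or enlarged heart, 1 rose and 0 fell at 48 h (5 and 0 adjusted over the list alone), with a median log2 change of 0.38 and a list test by camera at adjusted p = 2.37e-12; it also passed with an estimated correlation (adjusted p = 0.0217). Acta1, skeletal muscle actin, which adult heart muscle makes at low share and re-expresses under load, read 0.77 (SE 0.17, adjusted p = 0.127) with every TAC array above every sham array. It was called with scan day as a block (the same log2 change, adjusted p = 0.0348), with quantile (0.0163) or cyclic loess normalization and without TAC replicate 5. Nppa, atrial natriuretic peptide, read 1.17 (SE 0.59, adjusted p = 0.815), Myh7, the slow beta myosin heavy chain, 0.31 (0.917), Myh6, the fast alpha chain of adult mouse ventricle, 0.01 (0.996), Ankrd1, a stretch-responsive nuclear cofactor, 0.29 (0.824), and Atp2a2, the calcium pump of the sarcoplasmic reticulum, −0.07 (0.992). Nppa read 0.50 without TAC replicate 4, Myh7 0.09 without TAC replicate 1 and Ankrd1 0.44 without TAC replicate 5. Myh6 turned to −0.03 with quantile normalization and −0.01 with cyclic loess normalization.

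Lists of matrix, cytoskeletal and macrophage genes shifted upward at 48 h although none of their measured members passed over all genes or over the list alone, except 3 matrix proteases and inhibitors over the list alone. The median log2 change was 0.34 for 16 collagens (camera adjusted p = 9.31e-07, and adjusted p = 0.201 with an estimated correlation). Col1a1 and Col3a1, the main fibrillar collagens of heart, read 0.68 (adjusted p = 0.577) and 0.65 (0.799), and the basement membrane chains Col4a2 and Col4a1 0.11 and 0.31. The median was 0.17 for 37 matrix glycoproteins and assembly factors (0.00514, and adjusted p = 0.494 with an estimated correlation). Fn1, fibronectin, read 0.22 (0.891), Postn, periostin, 0.51 (0.873), Ccn2, connective tissue growth factor, 0.97 (0.691), and the small proteoglycans Dcn and Bgn −0.11 and 0.27. The median was 0.15 for 33 cytoskeletal genes (3.99e-05, and adjusted p = 0.184 with an estimated correlation), with Actg1, cytoplasmic actin, at 0.09 and Tln1, talin, at −0.05. It was 0.18 for 15 macrophage and monocyte markers (0.00173, and adjusted p = 0.115 with an estimated correlation), with the complement genes C1qa at 0.10 and C1qc at 0.24. Without TAC replicate 4 the medians of the collagens and the cytoskeletal genes were 0.21 and 0.09, and Col3a1 and Postn read 0.37 and 0.28. Without sham replicate 1 the cytoskeletal and macrophage medians were 0.10 and 0.09. Without sham replicate 4 the macrophage and glycoprotein medians were both 0.10, and without TAC replicate 1 the glycoprotein median was 0.10 and Ccn2 read 0.60.

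A smaller upward shift that also passed camera at 48 h was 0.07 for 20 matrix proteases and inhibitors (adjusted p = 0.0308, and adjusted p = 0.445 with an estimated correlation), with the lysosomal proteases Ctsd at 0.01 and Ctsb at −0.11. The median was 0.12 for 26 immediate early genes (0.0494, and adjusted p = 0.572 with an estimated correlation), with Jund at 0.01 and Btg2 at 0.15. Fatty acid oxidation genes shifted downward by a median of −0.10 over 31 genes (0.0124, and adjusted p = 0.572 with an estimated correlation). None of the 31 was called by limma and 1 was lower adjusted over the list alone, with Hadhb and Ech1 of the mitochondrial pathway at −0.10 and −0.19. The call of the matrix glycoproteins was lost without sham replicate 1 or TAC replicate 4 (adjusted p up to 0.0710). The protease call was lost without sham replicate 1, 2 or 4 or TAC replicate 1 or 4 (up to 0.217). Fatty acid oxidation lost its call without sham replicate 1 or 2 or TAC replicate 2 or 4 (up to 0.206), and the immediate early genes without sham replicate 2 or 4 or TAC replicate 1 or 2 (up to 0.745). The protease median was −0.00 and −0.02 without sham replicate 4 and TAC replicate 4, and 0.11, 0.16, 0.11 and 0.13 without sham replicates 2 and 3 and TAC replicates 2 and 3. That of the immediate early genes was 0.06, 0.03 and 0.27 without sham replicate 2, TAC replicate 1 and TAC replicate 5, and that of fatty acid oxidation −0.04 without TAC replicate 2.

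**Figure D2:**
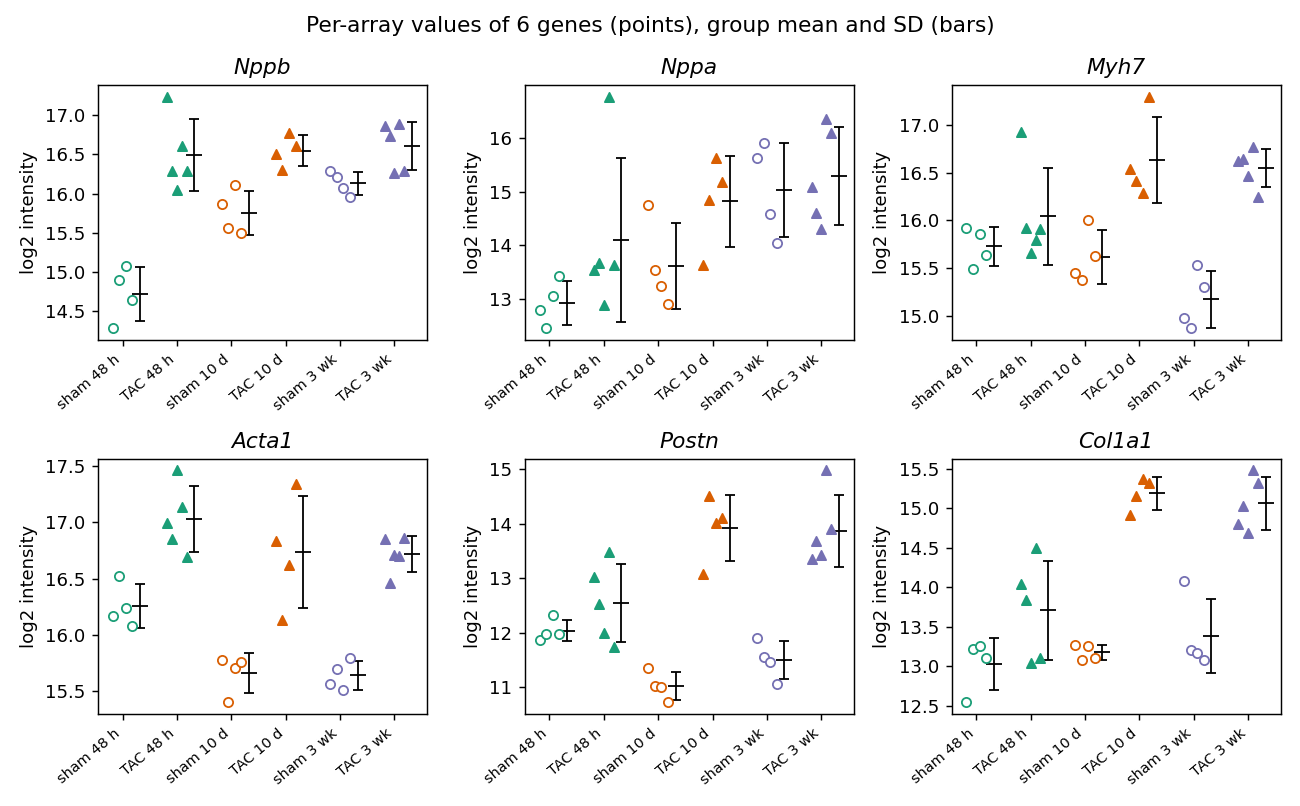
Log2 intensity of Nppb, Nppa, Myh7, Acta1, Postn and Col1a1 in each array (points), with the mean and SD of each group of 4 or 5 arrays, for sham and TAC at 48 h, 10 d and 3 wk. Mean Nppb rises over the sham groups from 14.73 to 15.76 and 16.13, while the TAC groups lie at 16.49, 16.55 and 16.61; Postn is at 13.93 and 13.87 in TAC and 11.02 and 11.49 in sham at 10 d and 3 wk.

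At 10 d the question was which transcripts differed once the load had lasted longer. Matrix genes made up most of the largest rises: Postn, a matricellular protein of activated fibroblasts, rose 7.48-fold (log2 2.90, SE 0.33, adjusted p = 1.42e-05; 13.93 ± 0.61 in TAC and 11.02 ± 0.26 in sham, SD, n = 4 each), Col5a2 5.40-fold, Col1a1 4.05-fold (SE 0.25, 2.73e-05; 15.19 ± 0.21 and 13.18 ± 0.10), Col3a1 3.95-fold and Eln, elastin, 3.93-fold. Of 15 macrophage and 20 endothelial markers 7 and 5 rose (9 and 6 adjusted over the list alone), with Cldn5, a tight junction protein of endothelium, at 2.48-fold (SE 0.17, 3.10e-05; 11.86 ± 0.13 and 10.55 ± 0.28). Of 31 fatty acid oxidation genes 9 fell (14 adjusted over the list alone), a list that did not pass with an estimated correlation, and the largest falls included Ces1d, a lipid-hydrolysing carboxylesterase (log2 −1.09, SE 0.20, adjusted p = 1.88e-03; 11.95 ± 0.42 and 13.05 ± 0.16). Of the 74 named genes that passed at 10 d, Bcl2l1 alone had TAC and sham arrays that overlapped. In the others all 4 TAC arrays lay on one side of all 4 sham arrays. The rule for named genes takes its largest changes from genes without overlap. Of all 280 genes called at 10 d by the probe set that represents them, 257 had no overlap.

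Over all genes, 355 probe sets of 308 genes were called at 10 d, 212 higher and 143 lower, of which 153 and 78 changed at least 1.5-fold. At an unadjusted p of 0.05, 1531 passed. TAC and sham arrays did not overlap in 891 genes, 16.0% where chance gives 2.86%. With scan day as a block, which rests on the 7 arrays of 1 day, 300 probe sets were called, 248 of the 355 among them, and all 355 kept their sign. Without TAC replicate 2, 3 or 4 or sham replicate 4, 1 or 2 the count was 187, 210, 215, 211, 225 and 234. It was 718 with array weights, 538 using only the groups compared and 11 with the unmoderated test.

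Of the 14 hypertrophy markers, 5 rose and 0 fell at 10 d (8 and 0 adjusted over the list alone). Their median was 0.49 (camera adjusted p = 4.33e-06, and adjusted p = 0.115 with an estimated correlation) and 0.48 with scan day as a block (3.27e-04). Rcan1, an inhibitor of calcineurin that calcineurin itself induces, rose by 1.38 (adjusted p = 3.96e-03), Fhl1, a sarcomere-associated LIM protein, by 1.24 (1.78e-03), Acta1 by 1.07 (SE 0.18, 5.47e-04) and Myh7 by 1.02 (SE 0.23, 7.97e-03), with blocked values of 1.36, 1.10, 0.87 and 0.80. The call of Myh7 was lost with the main scan day alone (adjusted p = 0.0507) and with the probe set of largest interquartile range (0.0625). Nppb rose by 0.79 (SE 0.21, adjusted p = 0.0249), with 0.77 and adjusted p = 0.0665 under the block, in a range of 0.00614 to 0.0893 over its alternatives. Nppa read 1.21 (SE 0.62, 0.270), Ankrd1 0.26 (0.398), Myh6 0.05 (0.909) and Atp2a2 0.13 (0.687). Ankrd1 read 0.44 without TAC replicate 2 and 0.14 without TAC replicate 4. Myh6 turned to −0.07 with quantile normalization and, with the block, Myh6 read −0.14 and Atp2a2 −0.02.

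Of the 16 collagens, 11 rose and 0 fell (12 and 0 adjusted over the list alone). Their median was 1.07 (camera adjusted p = 3.41e-16, and adjusted p = 0.0548 with an estimated correlation) and 1.04 with the block. Col5a2, which joins type I fibrils, rose by 2.43 (SE 0.40, adjusted p = 5.42e-04), Col1a1 by 2.02, Col3a1 by 1.98 (SE 0.33, 5.42e-04) and Col8a1, a short-chain collagen of vessel walls, by 1.78 (SE 0.28, 3.07e-04). Other probe sets of Col1a1 read 1.16 and of Col3a1 1.74 and 0.92. Of 37 matrix glycoproteins and assembly factors, 12 rose and 0 fell (16 and 1 adjusted over the list alone). Their median was 0.43 (1.83e-10, and adjusted p = 0.115 with an estimated correlation) and 0.43 with the block. Rises included Postn, Eln by 1.98 (SE 0.53, 0.0284), Ltbp2, a microfibril protein related to the binders of latent TGF-beta, by 1.75 (0.0219, with 2 sham arrays at the floor), and Sparc, a collagen-binding matricellular protein, by 1.57 (2.34e-04). Fn1 rose by 0.79 (1.99e-03), while Ccn2 read 1.03 (SE 0.41, 0.145, or 0.0238 using only the groups compared). Of 20 matrix proteases and inhibitors, 4 rose and 0 fell (5 and 0 adjusted over the list alone). Their median was 0.37 (2.9e-04, and adjusted p = 0.184 with an estimated correlation) and 0.27 with the block. Rises included the metalloproteinases Adam19 by 1.06 (0.0125) and Mmp14 by 0.90 (0.0125), and the cathepsins Ctsz by 1.00 (0.0221) and Ctss by 0.83 (3.54e-03).

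Of 18 fibroblast markers, 3 rose and 0 fell at 10 d (5 and 0 adjusted over the list alone). Their median was 0.16 (camera adjusted p = 0.00514, and adjusted p = 0.318 with an estimated correlation) and 0.12 with the block. Rises included Mfap5, a microfibril glycoprotein, by 1.56 (5.72e-04; its other probe set read −0.12), Meox1, a homeobox factor, by 1.42 (2.85e-04), and Lum, the collagen-binding proteoglycan lumican, by 0.88 (3.48e-04). Of 15 macrophage and monocyte markers, 7 rose and 0 fell (9 and 0 adjusted over the list alone). Their median was 0.46 (9.71e-08, and adjusted p = 0.0217 with an estimated correlation) and 0.45 with the block. Rises included Lyz2, lysozyme, by 0.80 (0.0194), Mpeg1, a pore-forming protein of phagocytes, by 0.74 (0.0395, or 0.111 with the block), C1qc by 0.63 (3.54e-03), and Tyrobp, a signalling adaptor of myeloid receptors, by 0.62 (0.0329). Of 20 endothelial markers, 5 rose and 0 fell (6 and 0 adjusted over the list alone). Their median was 0.24 (4.7e-05, and adjusted p = 0.0269 with an estimated correlation) and 0.23 with the block. Rises included Cldn5 by 1.31, Cd34, a surface sialomucin, by 1.29 (4.22e-04), Tie1, a receptor of the angiopoietin pathway, by 0.65 (0.0205), and Cdh5, VE-cadherin, by 0.62 (3.52e-03). Over all durations, the camera calls that held with an estimated correlation were these macrophage and endothelial calls at 10 d and the hypertrophy call at 48 h.

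Of 33 cytoskeletal genes, 11 rose and 0 fell at 10 d (21 and 1 adjusted over the list alone). Their median was 0.48 (camera adjusted p = 2.87e-11, and adjusted p = 0.0548 with an estimated correlation) and 0.44 with the block. Rises included Anxa2, a membrane and actin binding annexin, by 1.11 (5.87e-04), Tmsb10, an actin monomer binder, by 1.11 (1.95e-04), Capg, an actin filament capper, by 1.07 (0.0341), and Marcks, a membrane substrate of protein kinase C, by 1.05 (5.65e-04). Of 26 immediate early genes, 4 rose and 0 fell (9 and 1 adjusted over the list alone). Their median was 0.40 (5.28e-04, and adjusted p = 0.286 with an estimated correlation) and 0.37 with the block. Rises included Klf2, a flow-responsive factor of endothelium, 5.52-fold (log2 2.46, SE 0.57, 0.0113), Egr1 by 1.00 (0.0267), Ier2 by 0.84 (0.0470) and Jund by 0.55 (0.0189). Of 26 cell cycle genes, 2 rose and 0 fell (7 and 2 adjusted over the list alone). Their median was 0.37 (0.00173, and adjusted p = 0.124 with an estimated correlation). Rises included Cdc20, which activates the anaphase ubiquitin ligase, by 0.96 (3.20e-03), and cyclin Ccnd3 by 0.39 (0.0349, or 0.119 with the block).

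Of 31 fatty acid oxidation genes, 9 fell and 0 rose at 10 d (14 and 0 adjusted over the list alone). Their median was −0.37 (camera adjusted p = 4.56e-08, and adjusted p = 0.18 with an estimated correlation) and −0.36 with the block. Slc27a1, a fatty acid transporter, fell by 0.80 (adjusted p = 2.53e-03), Eci1, an enoyl-CoA isomerase, by 0.66 (7.15e-03), Ech1, a dienoyl-CoA isomerase, by 0.62 (0.0371, or 0.0567 with the block), and Crat, carnitine acetyltransferase, by 0.58 (3.54e-03). Of 17 glycolysis and glucose uptake genes, 1 rose and 2 fell (2 and 2 adjusted over the list alone). Pfkp, a phosphofructokinase isoform, rose by 1.01 (0.0182), while the muscle isoform Pfkm fell by 0.44 (0.0362, or 0.0494 with the block) and the insulin-responsive glucose transporter Slc2a4 by 0.46 (0.0188). Sdha, a subunit of succinate dehydrogenase, fell by 0.47 (0.0205, or 0.0738 with the block), as the 1 of 80 citric acid cycle and oxidative phosphorylation genes that passed (1 adjusted over the list alone).

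Single members of further lists passed at 10 d. Of 22 natriuretic, renin, adrenergic and endothelin genes, 3 rose and 4 fell (3 and 4 adjusted over the list alone). Ace, angiotensin-converting enzyme, rose by 1.02 (adjusted p = 3.22e-04) and the receptor kinase Grk5 by 0.57 (0.0366, or 0.0557 with the block). Rgs2, a brake on Gq signalling, fell by 1.16 (0.0369) and Corin, the protease that activates pro-atrial natriuretic peptide, by 0.80 (3.81e-03). In calcium handling, where 1 of 15 rose and 1 fell (1 and 4 adjusted over the list alone), Casq1, a calsequestrin, rose by 0.67 (6.96e-03) and Ryr2, the cardiac calcium release channel, fell by 0.43 (0.0329, or 0.0856 with the block). Of 31 antioxidant and detoxification genes, 2 rose and 2 fell (4 and 5 adjusted over the list alone). Mt2, a metallothionein, rose by 0.96 (0.0408, or 0.0629 with the block), and Txn1, thioredoxin, by 0.36 (0.0283). The glutathione transferases Gstk1 and Gstm2 fell by 0.77 (4.85e-03) and 0.59 (3.52e-03). Des, desmin, rose by 0.49 (0.0252; 1 of 17 sarcomere genes, 2 and 1 adjusted over the list alone). Fstl1, a secreted follistatin-like glycoprotein, rose by 1.32 (5.40e-04; 1 of 31 growth factor signalling genes, 4 and 0 adjusted over the list alone), and Il4ra, the interleukin 4 receptor, by 1.68 (0.0244, or 0.0707 with the block; 1 of 16 cytokine genes, 2 and 1 adjusted over the list alone). Pabpc1, a poly(A) binding protein, rose by 0.44 (0.0371, or 0.127 with the block; 1 of 30 translation genes, 2 and 0 adjusted over the list alone), and the death receptor Tnfrsf1a by 0.76 (2.29e-03, other probe set −0.30). Bcl2l1, an inhibitor of apoptosis, fell by 0.44 (0.0207, or 0.0685 with the block; with Tnfrsf1a, 1 rise and 1 fall among 19 apoptosis genes over all genes as adjusted over the list alone). Herpud1, an endoplasmic reticulum stress gene, fell by 0.67 (0.0407, or 0.105 with the block; 1 of 28 heat shock and stress genes, 1 adjusted over the list alone).

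Outside the lists, Serpinf1, a secreted antiangiogenic serpin, rose by 1.71 (adjusted p = 2.85e-04, other probe set −0.50). The largest falls were Kcnj12, an inward rectifier potassium channel, by 1.21 (0.0429, with 1 TAC array at the floor; −0.83 and 0.134 with the block), Gtf3c4, a subunit of an RNA polymerase cofactor, by 1.19 (8.49e-03), Rgs2, Rit2, a small GTPase, by 1.14 (1.21e-03), and Ces1d. Next came Klf17, a zinc finger factor, by 1.08 (0.0284), Slc7a2, a cationic amino acid transporter, by 1.05 (0.0197), Dsg2, a desmosomal cadherin, by 1.01 (1.55e-03), Fam83f by 0.98 (0.0405), and Hsd11b1, which regenerates active glucocorticoid, by 0.95 (2.11e-03).

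Of the 74 named genes that passed at 10 d, 61 stayed past the threshold with the block and all 74 kept their sign; the 13 others had adjusted p from 0.0557 to 0.134, and over all alternatives the 74 had adjusted p from 9.09e-07 to 0.530. Calls of 40 of the 74 held without each array in turn. Calls lost without sham replicates 1, 2, 3 and 4 numbered 18, 23, 18 and 26, and without TAC replicates 1, 2, 3 and 4 numbered 8, 26, 23 and 24. The 34 genes concerned, with the highest adjusted p without 1 array, were Adam19 (0.0503), Mmp14 (0.0575), Slc2a4 (0.0636), Pfkp (0.0699), Jund (0.0722), Sdha (0.0804), Ltbp2 (0.0811), Ctsz (0.0822), Egr1 (0.0840), Eln (0.0871), Lyz2 (0.0880), Slc7a2 (0.0886), Nppb (0.0893), Klf17 (0.0897), Tie1 (0.0908), Bcl2l1 (0.0911), Txn1 (0.0912), Capg (0.0982), Des (0.101), Il4ra (0.102), Mt2 (0.102), Rgs2 (0.104), Tyrobp (0.109), Pfkm (0.109), Mpeg1 (0.111), Ech1 (0.112), Ryr2 (0.115), Grk5 (0.121), Fam83f (0.125), Herpud1 (0.132), Ier2 (0.133), Ccnd3 (0.141), Pabpc1 (0.145) and Kcnj12 (0.166).

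**Figure D3:**
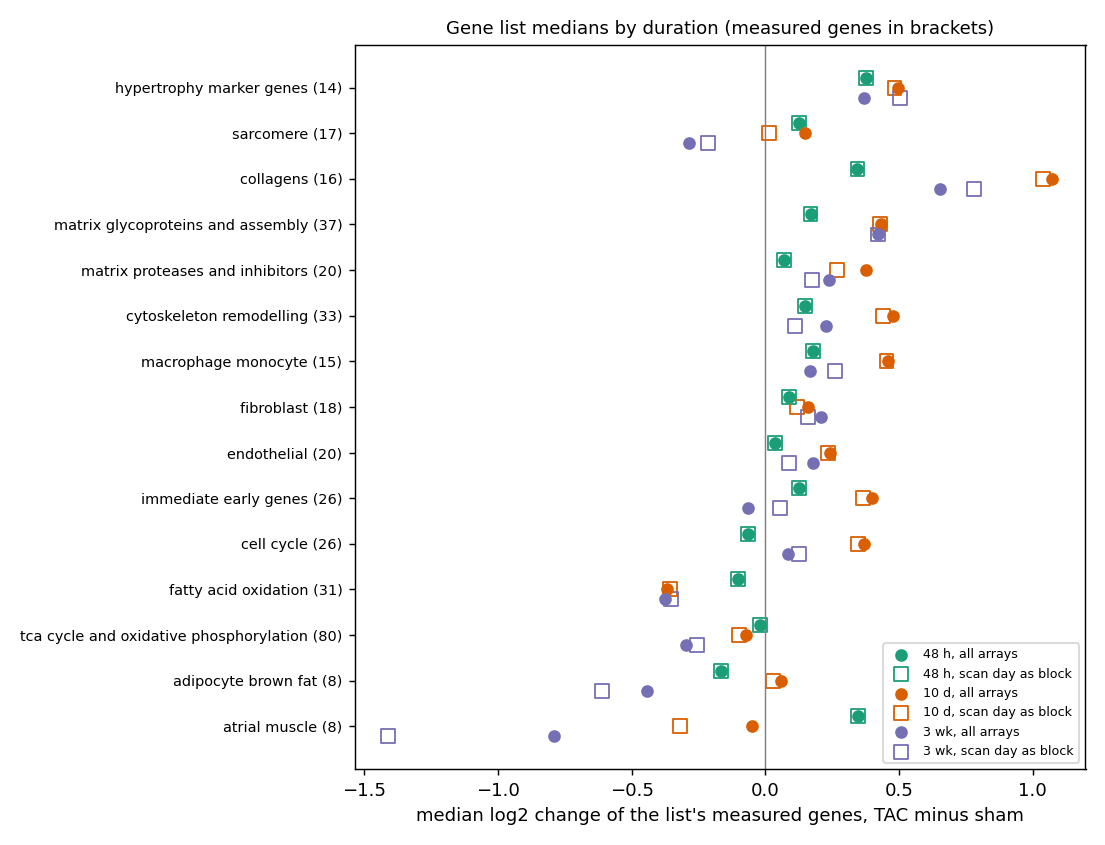
Median log2 change, TAC minus sham, of the measured genes of 15 lists at 48 h, 10 d and 3 wk; filled points use all arrays, open squares have scan day as a block, and the brackets give the measured genes. Collagens lie at 0.34, 1.07 and 0.65, and fatty acid oxidation genes lie at −0.10, −0.37 and −0.37.

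The comparison at 3 wk asked which transcripts differed late after constriction. Matrix genes were again among the largest rises, with Postn 5.19-fold (log2 2.38, SE 0.32, adjusted p = 2.24e-04; 13.87 ± 0.66 in TAC, SD, n = 5, and 11.49 ± 0.35 in sham, n = 4) and Col1a1 3.21-fold (SE 0.24, 3.17e-04; 15.06 ± 0.34 and 13.38 ± 0.46). Frzb, a secreted antagonist of Wnt signalling, rose 5.78-fold (SE 0.48, 2.75e-03; 10.31 ± 0.41 and 7.78 ± 0.26). Myh7 rose 2.60-fold (SE 0.21, 4.94e-04; 16.55 ± 0.20 and 15.17 ± 0.30) and Acta1 2.11-fold (SE 0.17, 5.18e-04; 16.72 ± 0.16 and 15.64 ± 0.13). Falls included 11 of 31 fatty acid oxidation genes and 7 of 80 citric acid cycle and oxidative phosphorylation genes (15 and 34 adjusted over the list alone), of which neither list passed with an estimated correlation. Ces1d fell by 1.34 (SE 0.19, 3.17e-04; 11.49 ± 0.44 and 12.83 ± 0.07). All 5 TAC arrays lay on one side of all 4 sham arrays in the named genes that passed at 3 wk, except Col5a2, Ltbp2, Ndufa6, Tgfb1, Adra1b and Ace. Of all 268 genes called at 3 wk by the probe set that represents them, 203 had no overlap.

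Over all genes, 345 probe sets of 299 genes were called, 218 higher and 127 lower, of which 148 and 64 changed at least 1.5-fold, and 1433 passed an unadjusted p of 0.05. TAC and sham arrays did not overlap in 496 genes, 8.91% where chance gives 1.59%. With scan day as a block, which rests on the 5 arrays of 1 day, 18 probe sets were called, 15 of the 345 among them; all 345 kept their sign, at a median of 0.52 in the called direction against 0.65 with all arrays. With the main scan day of each duration alone, which leaves those 5 arrays at 3 wk, 33 were called, without TAC replicate 4 168, without TAC replicates 4 and 5 91, and without sham replicate 4 229. Using only the groups compared gave 127 and the unmoderated test 3.

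With the block, 8 of the 62 named genes that passed stayed past the threshold: Postn (log2 1.98, adjusted p = 0.0403), Col1a1 (1.65, 0.0286), Col5a2 (2.00, 0.0418), Sparc (1.40, 0.00605), Lum (0.73, 0.0394), Myh7 (1.37, 0.0385), Acta1 (1.07, 0.0286) and Ces1d (−1.46, 0.0286). All 62 kept their sign. The 54 others had adjusted p from 0.0620 to 0.656 with the block, and over all alternatives the 62 had adjusted p from 2.08e-08 to 0.912. The blocked log2 change of each of the 54 follows its value with all arrays in the next paragraphs.

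Of the 14 hypertrophy markers, 5 rose and 0 fell at 3 wk (7 and 1 adjusted over the list alone). Their median was 0.37 (camera adjusted p = 1.63e-04, and adjusted p = 0.176 with an estimated correlation) and 0.50 with the block (9.02e-05). Besides Myh7 by 1.38 and Acta1 by 1.07, Fhl1 rose by 1.31 (adjusted p = 9.47e-04, blocked 0.86) and Rcan1 by 1.19 (8.36e-03, blocked 1.54). Nppb read 0.48 (SE 0.20, 0.165, or 0.0387 with quantile normalization), Nppa 0.26 (SE 0.59, 0.853, blocked −0.57), Ankrd1 0.14 (0.686), Atp2a2 −0.23 (0.407), and Myh6 −0.38 (0.132, or 0.0412 using only the groups compared), the last with every TAC array below every sham array.

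Of the 16 collagens, 8 rose and 0 fell (11 and 1 adjusted over the list alone). Their median was 0.65 (camera adjusted p = 2.32e-10, and adjusted p = 0.124 with an estimated correlation) and 0.78 with the block. Rises included Col5a2 by 1.97 (3.30e-03), Col1a1 by 1.68 (other probe set 0.70), Col8a1 by 1.29 (4.71e-03, blocked 0.90) and Col3a1 by 1.18 (SE 0.31, 0.0261, blocked 0.98, other probe sets 1.28 and 0.24). Of 37 matrix glycoproteins and assembly factors, 12 rose and 0 fell (16 and 1 adjusted over the list alone). Their median was 0.42 (2.26e-11, and adjusted p = 0.112 with an estimated correlation) and 0.42 with the block. Rises included Postn, Mfap4, a microfibril glycoprotein, by 2.01 (0.0198, blocked 2.03), Ltbp2 by 1.53 (0.0344, blocked 1.88) and Sparc by 1.48 (SE 0.23, 4.94e-04). Fn1 rose by 0.65 (7.41e-03, blocked 0.62), while Ccn2 read 0.79 (0.269), or 0.49 without TAC replicate 4. The 20 matrix proteases and inhibitors had a median of 0.24 (0.00714, and adjusted p = 0.318 with an estimated correlation) and of 0.17 with the block (0.329). None of them was called over all genes by limma and 4 were higher adjusted over the list alone, with Ctsd at −0.23 and Ctsb at 0.05. Without TAC replicate 4 the list test gave 0.0558.

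Of 18 fibroblast markers, 4 rose and 0 fell at 3 wk (5 and 0 adjusted over the list alone). Their median was 0.21 (camera adjusted p = 0.00514, and adjusted p = 0.318 with an estimated correlation) and 0.16 with the block (0.0945), or 0.12 and 0.10 without sham replicate 4 and TAC replicate 4. Rises included Frzb by 2.53 (blocked 2.21), Mfap5 by 1.38 (2.09e-03, blocked 0.93, other probe set −0.50), Lum by 0.97 (2.45e-04) and Pdgfra, a growth factor receptor of fibroblasts, by 0.62 (0.0378, blocked 0.42, other probe set −0.12). Of 15 macrophage and monocyte markers, 4 rose and 0 fell (5 and 0 adjusted over the list alone). Their median was 0.17 (0.0031, and adjusted p = 0.124 with an estimated correlation) and 0.26 with the block (0.0149). That median was 0.32, 0.27, 0.29 and 0.29 without sham replicates 1, 2, 3 and 4 and 0.32 without TAC replicate 3. Rises included Lyz2 by 0.66 (0.0393, blocked 0.42), Cd68, a lysosomal glycoprotein, by 0.63 (6.59e-03, blocked 0.45), C1qb by 0.61 (7.67e-03, blocked 0.48, other probe set −0.29) and C1qa by 0.35 (0.0121, blocked 0.29). Of 20 endothelial markers, Cd34 rose, by 0.98 (4.48e-03, blocked 0.60), and 0 fell (3 and 0 adjusted over the list alone). Their median was 0.18 (0.0413, and adjusted p = 0.184 with an estimated correlation) and 0.09 with the block (0.0728). That list call was lost without sham replicate 2 (0.0716), sham replicate 4 (0.105, with a median of 0.11) or TAC replicate 4 (0.0504). Of 33 cytoskeletal genes, 5 rose and 0 fell (10 and 0 adjusted over the list alone). Their median was 0.23 (4.02e-05, and adjusted p = 0.184 with an estimated correlation) and 0.11 with the block (0.0192). Rises included Capg by 1.82 (SE 0.28, 4.94e-04, blocked 0.91), Anxa2 by 0.77 (0.0102, blocked 0.35), Anxa1 by 0.61 (0.0410, blocked 0.32) and Tpm4, a tropomyosin, by 0.58 (0.0190, blocked 0.39).

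Of 31 fatty acid oxidation genes, 11 fell and 0 rose at 3 wk (15 and 0 adjusted over the list alone). Their median was −0.37 (camera adjusted p = 1.02e-13, and adjusted p = 0.0878 with an estimated correlation) and −0.35 with the block. Falls included Acot1, an acyl-CoA thioesterase, by 1.70 (9.82e-03, with 1 TAC array at the floor, blocked −0.87), Ech1 by 0.88 (2.72e-03, blocked −0.67), Slc27a1 by 0.87 (9.81e-04, blocked −0.57) and Eci1 by 0.82 (9.47e-04, blocked −0.68). Of 80 citric acid cycle and oxidative phosphorylation genes, 7 fell and 0 rose (34 and 0 adjusted over the list alone). Their median was −0.30 (1.29e-17, and adjusted p = 0.176 with an estimated correlation) and −0.26 with the block. Falls included the cytochrome oxidase subunits Cox7a1 by 0.50 (0.0306, blocked −0.47) and Cox5b by 0.41 (0.0162, blocked −0.41), the complex I subunit Ndufa6 by 0.39 (0.0299, blocked −0.40) and the complex III subunit Uqcrb by 0.38 (0.0471, blocked −0.37). The 8 measured markers of adipocytes had a median of −0.44 (0.0402, and adjusted p = 0.124 with an estimated correlation) and of −0.61 with the block (0.00659). None was called by limma over all genes or adjusted over the list alone, with Cebpa at −0.18 and Scd1 at −0.55. The list call was lost without sham replicate 3 (0.142, with a median of −0.22) or TAC replicate 3 (0.110).

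Members of further lists passed at 3 wk. Of 22 natriuretic, renin, adrenergic and endothelin genes, 4 rose and 1 fell (4 and 2 adjusted over the list alone). Ace rose by 0.64 (adjusted p = 0.0127, blocked 0.52), Grk5 by 0.57 (0.0274, blocked 0.48) and Mef2d, a transcription factor of muscle, by 0.44 (0.0374, blocked 0.39). The alpha-1B adrenergic receptor Adra1b fell by 1.35 (0.0103, blocked −1.22). Of 31 growth factor signalling genes, 3 rose and 0 fell (3 and 1 adjusted over the list alone). Tgfb1, a driver of fibroblast activation, rose by 1.13 (0.0179, blocked 1.42, and 0.72 without sham replicate 3), Fstl1 by 1.02 (4.48e-03, blocked 0.81) and Fgfr1 by 0.77 (0.0300, blocked 0.52). Of 16 cytokine, chemokine and adhesion genes, 2 rose and 0 fell (2 and 0 adjusted over the list alone). Ccl8, a monocyte chemoattractant, rose by 2.27 (4.39e-03, with 1 sham array at the floor, blocked 1.60), and Cxcl12 by 0.48 (7.16e-03, blocked 0.42). In calcium handling, 1 of 15 rose and 1 fell (1 and 1 adjusted over the list alone). Casq1 rose by 0.72 (3.01e-03, blocked 0.68) and Cacnb2, a calcium channel subunit, fell by 0.59 (4.28e-03, blocked −0.47). In glycolysis and glucose uptake, 1 of 17 rose and 1 fell (1 and 5 adjusted over the list alone). Pfkp rose by 1.09 (7.16e-03, blocked 0.79) and Pfkm fell by 0.49 (0.0134, blocked −0.24). The cyclin Ccnd1 rose by 0.66 (2.23e-03, blocked 0.59; 1 of 26 cell cycle genes, 1 adjusted over the list alone). Gstk1 fell by 0.62 (0.0166, blocked −0.62; 1 of 31 antioxidant genes, 1 and 4 adjusted over the list alone). So did Endog, a mitochondrial nuclease, by 0.73 (0.0125, blocked −0.56; 1 of 19 apoptosis genes), Manf, an endoplasmic reticulum stress factor, by 0.57 (0.0167, blocked −0.38; 1 of 28 heat shock and stress genes), and the clock repressor Cry2 by 0.54 (0.0495, blocked −0.58; 1 of 12 clock genes), each list also with 1 adjusted over the list alone.

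Outside the lists, rises included Comtd1, a methyltransferase-like protein, by 1.67 (adjusted p = 0.0326, with 1 sham array at the floor, blocked 0.75), Adcy3, an adenylyl cyclase, by 1.52 (0.0223, blocked 1.51), and the phosphatase Ptpn18 by 1.41 (3.57e-03, blocked 0.65). Falls included Fbp2, the muscle fructose bisphosphatase, by 1.63 (0.0114, with 1 TAC array at the floor, blocked −1.18, and −1.08 without TAC replicate 4), A4galt, a glycolipid galactosyltransferase, by 1.34 (0.0262, blocked −0.94), Pla2g5, a secreted phospholipase, by 1.27 (7.16e-03, blocked −1.02), Slc22a12, a urate transporter, by 1.20 (0.0274, blocked −0.86), Abr by 1.08 (0.0126, blocked −1.19), and Ankrd11, a chromatin regulator, by 1.07 (0.0223, blocked −1.21).

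Calls of 34 of the 62 named genes at 3 wk held without each array in turn. Calls lost without sham replicates 1, 2, 3 and 4 numbered 14, 15, 18 and 18, and without TAC replicates 1, 2, 3, 4 and 5 numbered 2, 6, 3, 23 and 14. The 28 genes concerned, with the highest adjusted p without 1 array, were Endog (0.0515), Pfkm (0.0535), Ace (0.0545), Manf (0.0575), Anxa2 (0.0586), Gstk1 (0.0651), Cox5b (0.0660), Adra1b (0.0664), Ankrd11 (0.0697), Mfap4 (0.0759), Tpm4 (0.0759), Slc22a12 (0.0805), A4galt (0.0806), Tgfb1 (0.0868), Adcy3 (0.0875), Grk5 (0.0944), Col3a1 (0.107), Pdgfra (0.107), Mef2d (0.111), Ndufa6 (0.116), Fgfr1 (0.123), Cox7a1 (0.123), Ltbp2 (0.123), Comtd1 (0.138), Uqcrb (0.142), Cry2 (0.144), Lyz2 (0.149) and Anxa1 (0.153).

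The other lists did not pass camera at the durations given here, with medians at 48 h, 10 d and 3 wk in that order. Sarcomere genes had medians of 0.13, 0.15 and −0.29 (adjusted p = 0.0595, 0.117 and 0.0671), with Tnni3 and Mybpc3, a troponin and a myosin binding protein, at −0.35 and −0.32 at 3 wk. The sarcomere median at 48 h was 0.02 and 0.20 without TAC replicates 3 and 2, and at 10 d 0.01 with the block or without TAC replicate 4 and 0.36 without TAC replicate 2. Calcium handling genes had −0.02, −0.13 and 0.10 (0.631, 0.576 and 0.998). Ion channels and connexins, 17 measured, had −0.07, −0.22 and −0.20 (0.432, 0.191 and 0.0754), and glycolysis genes −0.01, 0.04 and −0.13 (0.954, 0.86 and 0.377). Cytokines had 0.14, 0.06 and 0.07 (0.197, 0.523 and 0.227), and growth factor signalling 0.10, 0.12 and −0.07 (0.152, 0.0671 and 0.954). The cytokine median at 48 h ran from 0.02 to 0.23 without each array in turn, and that of growth factor signalling at 10 d was 0.24 with the block. Natriuretic, renin, adrenergic and endothelin genes had 0.04, −0.14 and −0.22 (0.331, 0.631 and 0.48). Heat shock and stress genes had 0.06, −0.00 and −0.10 (0.152, 0.954 and 0.227), antioxidant genes −0.02, −0.07 and 0.04 (0.921, 0.452 and 0.804), and 28 protein degradation genes −0.03, −0.02 and −0.01 (0.729, 0.998 and 0.998). Translation genes had 0.06, 0.08 and 0.01 (0.0509, 0.0698 and 0.953), apoptosis genes −0.05, −0.01 and 0.02 (0.882, 0.86 and 0.954), and 12 clock genes −0.24, −0.17 and 0.03 (0.0509, 0.466 and 0.814). Citric acid cycle and oxidative phosphorylation genes read −0.02 and −0.07 at 48 h and 10 d (0.466 and 0.0671), cell cycle genes −0.07 and 0.08 at 48 h and 3 wk (0.333 and 0.31), and immediate early genes −0.06 at 3 wk (0.841).

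Markers of further cell types did not pass camera either. Atrial muscle markers, 8 measured, had medians of 0.35, −0.05 and −0.79 (adjusted p = 0.0775, 0.953 and 0.0775), with Myl7, the atrial light chain, at −2.33 (SE 1.41, adjusted p = 0.379) at 3 wk. The 48 h median was −0.16 without TAC replicate 4 and 0.70 without TAC replicate 1, and the 10 d median −0.38 and 0.65 without sham replicates 4 and 1. Smooth muscle and pericyte markers, 10 measured, had 0.03, 0.15 and 0.06 (0.953, 0.0754 and 0.729). Lymphocyte markers, 9 measured, had −0.12, −0.01 and −0.29 (0.631, 0.771 and 0.576), and 5 neutrophil and mast cell markers −0.27, −0.22 and −0.12 (0.466, 0.529 and 0.86). Erythroid markers, 9 measured, had −0.02, 0.23 and −0.19 (0.729, 0.954 and 0.998), and 11 skeletal muscle markers −0.01, −0.12 and −0.19 (0.729, 0.954 and 0.136). Lung epithelial markers, 4 measured, had 0.00, 0.01 and −0.09 (0.954, 0.974 and 0.953), and 5 Schwann cell and neuron markers 0.21, −0.13 and −0.29 (0.227, 0.954 and 0.44). Fibroblast and endothelial markers at 48 h had 0.09 and 0.04 (0.339 and 0.953), and adipocyte markers at 48 h and 10 d −0.17 and 0.06 (0.322 and 0.957). With scan day as a block, 3 of these lists passed: atrial muscle at 3 wk (−1.41, 0.0216), the citric acid cycle list at 10 d (−0.10, 0.0103) and clock genes at 48 h (0.0293). In at least 1 other alternative these 3 passed as well, as did sarcomere, ion channel, growth factor signalling, translation, smooth muscle and Schwann cell lists at some duration.

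Median, mean and test differed in sign for some lists that did not pass. The median alone was negative for calcium handling, glycolysis, antioxidant and skeletal muscle genes at 48 h, for atrial and heat shock genes at 10 d and for protein degradation at 3 wk. The median alone was positive for clock, apoptosis and translation genes at 3 wk. The mean alone differed in sign for erythroid markers at 10 d and 3 wk, growth factor signalling at 3 wk, protein degradation at 10 d and lung markers at 10 d. The test alone differed in sign for glycolysis and apoptosis at 10 d, antioxidant genes at 3 wk and smooth muscle at 48 h.

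Durations were compared by testing whether the TAC effect itself differed. Between 48 h and 10 d the effect rose for Postn by 2.39 on the log2 scale (SE 0.46, adjusted p = 0.0216), for Cldn5 by 1.33 (SE 0.23, 0.0106) and for H2az1, a histone variant, by 1.16 (SE 0.22, 0.0216). It rose too for Cd93, a receptor of endothelium, by 1.07 (SE 0.18, 0.0106) and for the basement membrane collagen Col4a1 by 1.00 (SE 0.19, 0.0216). It fell for Art3, an ADP-ribosyltransferase-like surface protein, by 1.12 (SE 0.18, 0.0106). Between 10 d and 3 wk the effect on Cldn5 fell by 1.46 (SE 0.23, adjusted p = 0.00514). With these, 1 probe set of no single gene (chosen after its values were seen) had an effect that rose by 0.86 between 48 h and 10 d and fell by 1.04 between 10 d and 3 wk.

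Those 7 probe sets for 10 d against 48 h (6 higher, 1 lower) were called among 770 at an unadjusted p of 0.05, the 2 for 3 wk against 10 d among 612, and 0 were called by limma for 3 wk against 48 h, with 820 at an unadjusted p of 0.05 and a lowest adjusted p of 0.0717. The last count was 10 with a stricter filter, 2 with scan day as a block or the atrial marker covariate and 17, 3, 3 and 1 without 3 wk TAC replicate 1, 3 wk sham replicate 3, 3 wk TAC replicate 2 and 48 h sham replicate 3. With scan day as a block the 6 genes stayed called for 10 d against 48 h (Postn 0.0407, Cldn5 0.0248, H2az1 0.0053, Cd93 0.0407, Col4a1 0.0448, Art3 0.0267; range over all alternatives 0.00215 to 0.0998), and the fall of Cldn5 to 3 wk read −1.27 (0.111; range 0.00158 to 0.111). Postn was no longer called without 48 h sham replicate 3, 48 h TAC replicate 3, 10 d sham replicate 2 or 4, or 10 d TAC replicate 2, 3 or 4 (up to 0.0820). H2az1 lost its call without 10 d sham replicate 1 or 4 or 10 d TAC replicate 2 (up to 0.0660), and Col4a1 without 48 h sham replicate 2, 10 d sham replicate 1, or 10 d TAC replicate 2 or 3 (up to 0.0662). The count of 7 was 22, 17, 15, 11 and 11 without 10 d TAC replicate 1, 48 h TAC replicate 4, 48 h sham replicate 1, 48 h TAC replicate 1 and 10 d sham replicate 3, and 4 without 10 d sham replicate 4, 10 d TAC replicate 2 or 10 d TAC replicate 3. It was 34 with array weights, 24 with a stricter filter, 15 with scan day as a random block and 4 without an intensity trend. The count of 2 was 4 with no filter, with scan day as a fixed block or with the atrial marker covariate.

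By camera on the difference of effects, lists that shifted upward from 48 h to 10 d were collagens (median difference 0.75, adjusted p = 7.61e-09), matrix glycoproteins (0.30, 9.69e-06), cell cycle (0.45, 3.75e-04), cytoskeleton (0.30, 1.23e-04), macrophage (0.38, 0.00332) and endothelial genes (0.30, 3.01e-04). Fatty acid oxidation shifted downward (−0.25, 5.39e-04). From 10 d to 3 wk, collagens (−0.40, 0.00234), sarcomere (−0.43, 3.01e-04), citric acid cycle and oxidative phosphorylation (−0.24, 7.61e-09), immediate early (−0.55, 1.23e-04), cytoskeletal (−0.17, 0.0043) and macrophage genes (−0.15, 0.0425) shifted downward. From 48 h to 3 wk, collagens (0.30, 0.00332) and matrix glycoproteins (0.22, 9.69e-06) shifted upward. Shifts downward over the same span were those of sarcomere (−0.37, 0.00338), fatty acid oxidation (−0.35, 4.29e-07), citric acid cycle and oxidative phosphorylation (−0.25, 3.70e-12) and atrial genes (−1.18, 0.0069). None of these held with an estimated correlation, the lowest being adjusted p = 0.153 with an estimated correlation for endothelial genes from 48 h to 10 d.

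Probe sets called at 10 d and 3 wk overlapped: 76 were higher at both durations where 6.33 would be shared by independent lists (Fisher's exact p = 3.05e-65), 33 were lower at both where 2.49 would be (6.74e-29), and 0 moved in opposite directions. The 2 durations have separate sham arrays. Log2 changes correlated across probe sets at r = 0.437 (rho 0.411) between 10 d and 3 wk, 0.214 (0.167) between 48 h and 10 d and 0.130 (0.113) between 48 h and 3 wk. Here too, genes are not independent replicates. Of the 212 probe sets higher at 10 d, 166 (78.3%) were higher at 48 h, by a median of 0.15, and 195 (92.0%) at 3 wk, by a median of 0.44. Between 48 h and 10 d, 1 probe set higher at both was shared (0.116 expected, Fisher's exact p = 0.111), and between 48 h and 3 wk also 1 (0.12 expected, 0.114).

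**Figure D4:**
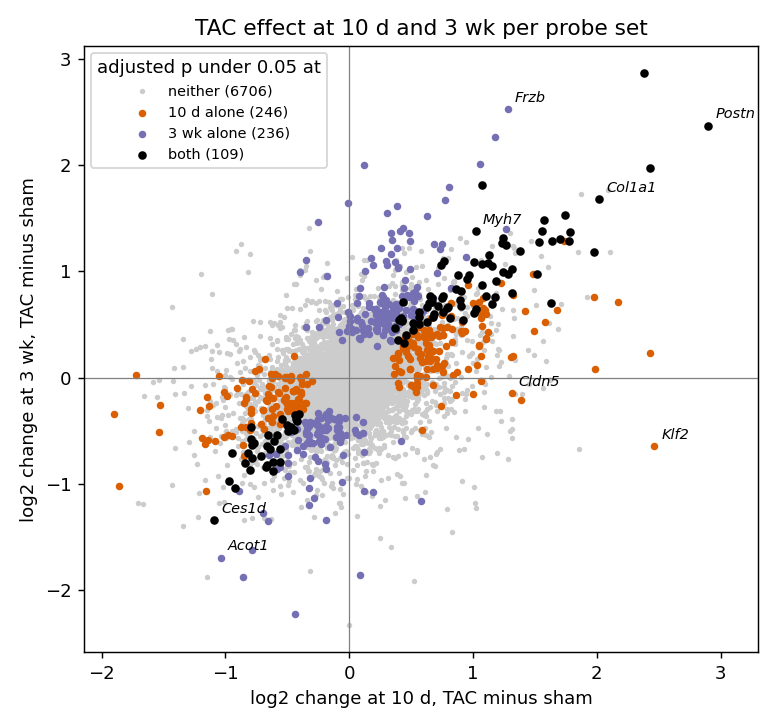
Log2 change at 3 wk against log2 change at 10 d, TAC minus sham, for the 7297 tested probe sets, coloured by the duration at which the adjusted p was under 0.05. Called at both durations were 109, at 10 d alone 246, at 3 wk alone 236 and at neither 6706; Postn lies at 2.90 and 2.38, Ces1d at −1.09 and −1.34.

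Sham hearts of different durations differed as background to these effects. An F test across the 3 sham groups called 2449 probe sets of 2057 genes (33.6%). Tested pairwise, each with its own adjustment, 1580 were called between 10 d and 48 h (835 higher, 745 lower) and 2427 between 3 wk and 48 h (1388 higher, 1039 lower). Ppara, the nuclear receptor that drives fatty acid oxidation genes, was higher than at 48 h by 2.23 at 10 d and 1.35 at 3 wk, and Apobec2, a muscle deaminase relative, by 1.73 and 2.76. Bnip3, a hypoxia-induced mitophagy receptor, was lower, at −1.80 and −1.66, Atp1b3, a sodium pump subunit, at −1.08 and −1.07, Polr2m at −1.02 and −1.12, and Dnajc10, a chaperone of the endoplasmic reticulum, at −1.09 and −1.41 (adjusted p of the F test from 9.76e-10 to 2.10e-08). Scan day and duration cannot be told apart here; with scan day as a random block 1573 were called by the F test, and with the unmoderated test 1108.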

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

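Tests chosen only after the result was seen were those of a scan-day difference unrelated to TAC and of scan day as the source of the 3 wk effect, the relation of Nppa to atrial markers over all arrays and in sham arrays, the slope of sarcomere genes on atrial markers, scaling and scan day as sources of the differences between sham groups, and the Arntl, Dbp and Tef test; the test in sham arrays replaced a comparison of the spread of the atrial markers (pooled SD 0.746 in sham, 1.30 in TAC) after those SDs were seen, and the scan-day source test replaced one that could not have decided.

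A sample far from the others of its group was found in 17 of 182 groups of values (9.34%). Chance flags about 1 in 20 groups. At 48 h, TAC replicate 4 read 16.78 for Nppa (others 12.88 to 13.66) and TAC replicate 1 read 16.93 for Myh7 (15.66 to 15.92), and the log2 3′ to 5′ ratio of Actb was 0.236 in sham replicate 2 (−0.435 to −0.326). At 10 d, TAC replicate 1 was low for Col5a2 at 12.32 (13.14 to 13.26), Col3a1 at 13.41 (14.17 to 14.25) and Ccn2 at 13.08 (14.15 to 14.21), sham replicate 3 for Col8a1 at 10.99 (11.24 to 11.27) and TAC replicate 4 for Kcnj12 at 7.39, the floor (8.83 to 8.93). TAC replicate 4, the 10 d array of another scan day, lay at 14.7 on PC1 (7.32 to 7.88). At 3 wk, TAC replicate 4 read 11.71 for Capg (10.75 to 10.97), 8.99 for Pla2g5 (10.66 to 10.88), 15.06 for Ech1 (15.90 to 16.18) and 11.45 for Slc27a1 (12.14 to 12.30). Sham replicate 1 read 14.07 for Col1a1 (13.08 to 13.20), 11.84 for Fn1 (11.38 to 11.43) and 24.4 on PC1 (18.0 to 19.0), and sham replicate 2 read 17.19 for Myh6 (17.31 to 17.32).

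A TAC effect that differed between durations by the interaction test was found for Postn (2.39 higher at 10 d than at 48 h, log2), Cldn5 (1.33), H2az1 (1.16), Cd93 (1.07), Col4a1 (1.00) and Art3 (−1.12), and for Cldn5 between 10 d and 3 wk (−1.46).

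Other splits of the same arrays show how often a division by chance gave as many calls, with the real split counted. At 10 d, where all 35 splits were run, only the real one gave as many (355 calls, highest other 11). For the other comparisons 100 splits were run, not all that exist. Only the real one gave as many at 3 wk (345 calls, highest other 298) and for the sham groups (2449, highest other 1977). Chance is thus unlikely for these 3, at a resolution of 1 in 35 or 1 in 100. For the difference of 10 d from 48 h, 4 of 100 gave as many (7 calls, highest other 143), so chance is not excluded. Nor is it for 48 h (4 calls, 6 of 100, highest other 68) or for the difference of 3 wk from 10 d (2 calls, 5 of 100, highest other 8). For that of 3 wk from 48 h limma called 0, so every split gives as many and the splits cannot tell; the highest other gave 98. The split of 48 h with 68 calls, several times the real count, set sham replicates 1 and 2 with TAC replicates 1, 3 and 4. These arrays lay at −9.67 to 4.86 on PC2 and the other 48 h arrays at 4.94 to 12.8. What lies behind that structure was not tested. PC2 also parts TAC from sham arrays at 10 d, so an uneven TAC effect is not excluded. For the splits with 143 and 98 calls the structure can be the TAC effect of 1 duration itself, which was not told apart. The 3 wk split with 298 calls moved only TAC replicate 1 to the sham side. Parting the 3 wk arrays by their main scan day gave 0 calls by limma. Both sides of that split hold TAC and sham arrays, so a TAC effect widens the spread within them. The side without the main scan day also mixes the second day with arrays of unknown day. The split therefore cannot tell how much scan day matters, and the blocked 3 wk count of 18 comes from another model.

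The 3 wk calls were few within 1 scan day: 31 with its 2 sham and 3 TAC arrays beside the other durations, against 345 with all arrays. Scan day as the source of the whole 3 wk effect is argued against by the probe sets called within 1 scan day at 10 d: their median 3 wk change within 1 scan day, in the 10 d direction, was 0.325 (233 of 280 the same way, 83.2%; highest of the other 10 splits of the arrays, real one counted, 0.116). Fewer arrays may account for the low count, since 4 of 60 sets of 2 sham and 3 TAC arrays, the real set counted, gave as few (19 to 449, median 100). Sets with 0, 1 and 2 TAC arrays of the second scan day gave medians of 35.5, 66.5 and 211.5 (6, 36 and 18 sets). A scan-day difference unrelated to TAC stays open: the second scan day minus the first correlated across probe sets with the 10 d effect at r = 0.299, where the highest of the other ways to part the 5 TAC arrays, 10 in all, gave 0.336, and with 2 arrays on that day a stronger TAC effect in them cannot be told apart from the day.

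Nppa varied widely between arrays (12.45 to 15.91 over the sham arrays and 12.88 to 16.78 over the TAC arrays of all durations). Array quality that lowers all muscle transcripts alike is argued against by a slope of the sarcomere mean on the atrial marker mean of 0.0492 (SE 0.0323). Induction of atrial genes by TAC as the only source of the spread is argued against by the relation of Nppa to the other atrial markers within 12 sham arrays. There r was 0.904 (permutation p = 0.00153, adjusted 0.00229) and rho 0.930 (permutation p = 0.00224, adjusted 0.00336), with r = 0.861 without the 2 farthest arrays. No scan day holds more than 4 sham arrays, too few for a value. Sham arrays cannot tell whether TAC adds to the spread in TAC arrays. The pooled SD of the atrial marker mean was 0.746 in sham and 1.30 in TAC arrays. A varying share of atrial muscle may account for the spread: deviations of Nppa within groups followed those of 7 other atrial markers over 26 arrays (r = 0.862, permutation p = 7.00e-05, adjusted 2.1e-04; rho 0.809, p = 5.00e-05, adjusted 1.5e-04; r = 0.768 without the 2 farthest; 0.871 within the 9 arrays of the 48 h scan day and 0.978 within the 7 of the 10 d scan day), with Myl7 from 10.02 to 16.41 in sham and 7.39 to 16.55 in TAC arrays, Myl4 from 9.59 to 16.30 and 8.61 to 16.83, and the ventricular light chain Myl2 from 15.63 to 17.36 and 15.62 to 17.73. Array quality in general stays open (atrial against sarcomere mean, r = 0.330, permutation p = 0.154; rho 0.402, p = 0.0741; r = 0.293 without the 2 farthest; 0.357 and 0.110 within the 48 h and 10 d scan days), among 3 relations computed in this family. What tissue was taken from each heart is not given in the labels beyond mouse heart.

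Sham groups of different durations differed in 2449 probe sets. Scaling between arrays as the whole source is argued against by 2223 calls after quantile normalization, and time of day at harvest, as the source of the whole difference, by the clock genes, of which 3 of 12 (25.0%) were called against 33.9% of all genes (one-sided Fisher's exact p = 0.830). For the 3 called, Arntl, Dbp and Tef, the sham change at 3 wk was 1.57, −0.90 and −0.44. For these, a time of day shared by TAC and sham hearts is argued against by the TAC arrays. Arntl minus the mean of Dbp and Tef was 2.24 higher at 3 wk than at 48 h in sham arrays. In TAC arrays that difference was −0.12 (exact permutation p = 0.897, n = 5 per group). From 48 h to 10 d it was −0.30 in sham and −1.82 in TAC arrays. Harvest of TAC and sham hearts at different times of day was not tested, and these values do not exclude it. Scan day cannot be told apart from duration, since no known day holds more than 1 duration; as a random block it left 1573 calls. Age and time since surgery go with duration in the same way and were not tested.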

How the results depend on the processing

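Tests chosen only after the data were seen were the main scan day of each duration alone, the 3 wk comparison without both TAC arrays of the second scan day, and the atrial marker covariate.

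All 355 and 345 probe sets called at 10 d and 3 wk kept their sign with scan day as a block, and scaling changed neither count by over 1.5 times. Without each array in turn the counts ran from 1 to 8 at 48 h, 187 to 389 at 10 d, 168 to 448 at 3 wk, 4 to 22 for 10 d against 48 h, 2 to 3 for 3 wk against 10 d and 0 to 17 for 3 wk against 48 h. The lowest and highest came without TAC replicate 4 and TAC replicate 5 at 48 h. Fewer arrays are compared there; otherwise the cause was not tested. With no filter, 4 were called for 3 wk against 10 d. A stricter filter gave 24 for 10 d against 48 h and 10 for 3 wk against 48 h. Without an intensity trend 1 was called at 48 h and 4 for 10 d against 48 h. Array weights gave 718 at 10 d and 34 for 10 d against 48 h. Using only the groups compared gave 1, 538 and 127 at 48 h, 10 d and 3 wk. A fold of at least 1.5 as well gave 2, 231 and 212. The unmoderated test per probe set, which estimates each spread from 8 or 9 arrays, gave 0, 11 and 3, and 1108 for the sham groups.

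Scan day as a fixed block gave 18 at 3 wk, 4 for 3 wk against 10 d and 2 for 3 wk against 48 h; the 3 wk estimate then rests on 5 arrays. As a random block it gave 15 for 10 d against 48 h and 1573 for the sham groups. The main scan day alone gave 33 at 3 wk, and leaving out both 3 wk TAC arrays of the second scan day 91. The atrial marker covariate gave 4 for 3 wk against 10 d and 2 for 3 wk against 48 h. Replicate numbers do not pair the arrays: over 12 pairs r ran from −0.13 to 0.03, and 0 sham arrays correlated best with the TAC array of their number. With replicate number as a block 8 were called at 48 h.

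Of values not called, Myh6 turned negative at 48 h with quantile (−0.0309) and cyclic loess normalization (−0.0121) and the replicate block (−0.0314), and at 10 d with quantile normalization (−0.0689), array weights (−0.0158) and, by scan day as a block or the main scan day alone, at −0.142. By these last 2, Atp2a2 at 10 d read −0.0203 and Nppa at 3 wk −0.574, and Nppa read −0.369 without both TAC arrays of the second scan day. Without each array in turn, Myh6 ran from −0.142 to 0.177 at 10 d and −0.0516 to 0.107 at 48 h, Atp2a2 from −0.0203 to 0.255 and −0.177 to 0.00965, Nppa at 3 wk from −0.0760 to 0.547, and the median of the matrix proteases at 48 h from −0.0165 to 0.159. The probe set of largest interquartile range, another probe set of the gene, read −0.305 for Tnfrsf1a at 10 d, −0.290 for C1qb and −0.116 for Pdgfra at 3 wk and −0.0300 for Itgav at 48 h. The cause was not tested for any of these.

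Of 30 called list medians, 1 changed sign in an alternative, and of 72 not called, 41 did. With an estimated correlation 3 of the 30 list calls passed. The stricter filter lost 7 list calls and gained 1, and a floor at the 40th percentile lost 3 and gained 2. No filter, the probe set of largest interquartile range and scan day as a fixed block each lost 3 and gained 3. Among 28 alternatives at 3 wk, the endothelial list was called in 17 and the adipocyte list in 21. Of the values of named genes, calls were lost in 68 with scan day as a fixed block, 68 of 136 with the main scan day alone, 40 with only the groups compared, 37 of 62 without both arrays of the second scan day, 32 with no filter, 16 with no intensity trend, 16 with the replicate block, 9 with array weights, 9 with the probe set of largest interquartile range besides the reversals above, 8 with a random block, 6 each with quantile normalization, cyclic loess normalization and a floor at the 40th percentile, 3 with median centring, and 1 each with a floor at the 5th percentile and the covariate. None of 146 was lost with an offset in place of the floor or robust eBayes, and none of the 108 that the stricter filter left to test. For arrays, signal over background limits the lowest probe sets: values at the floor enter Kcnj12, Ltbp2, Ccl8, Comtd1, Acot1 and Fbp2.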

Other observations

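The covariate test of Nppa was chosen after the spread of Nppa was seen, though its prediction was written before its value was known.

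Nppa, a standard marker of pressure load, passed at no duration (log2 1.17, 1.21 and 0.26; adjusted p = 0.815, 0.270 and 0.853 at 48 h, 10 d and 3 wk). The hypothesis was that a TAC effect on Nppa may be hidden by a varying amount of atrial muscle. With the mean of Myl7 and Myl4 per array as a covariate, centred within each group, the log2 changes stay the same by construction and the SE at 10 d fell from 0.62 to 0.35. The lowest adjusted p over the durations was then 0.0434, at 10 d, in a range of 0.0434 to 0.506 over its 26 alternatives, of which this was the 1 that called it; at 48 h and 3 wk it was 0.254 and 0.723. With a covariate centred this way, a difference in atrial muscle between the TAC and sham groups stays in the log2 change. Its spread within groups leaves the SE, so the adjusted p can be too low and does not decide the question. The atrial markers were also chosen after the same arrays had been seen. A hidden TAC effect on Nppa therefore stays a hypothesis, and hearts dissected into atria and ventricles would test it.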
